A study of Mus musculus with 4 samples.

How the data were processed

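Single cells were sorted into 384-well plates and profiled with MARS-seq, a 3' method that gives each molecule a UMI, from mice aged 8 weeks per the labels. The cells were from a DC-enriched lymph node fraction, gated as positive for CD45 and MHC class II and negative for markers of T cells, B cells, NK cells, neutrophils and plasmacytoid DC. There were 4 plates in 2 groups, OVA/CpG and BSA/CpG, with replicate numbers 1 and 2 in each group from the labels. The deposited values are raw counts per gene and well, not normalized, with ERCC spike-in rows included. The submitters' processing notes name bcl2fastq 2.15.0.4 and genome build mm9. The aligner, the annotation and the rule for collapsing molecules are not given in the sources used here. The authors also deposited a table of wells with the plate, the sequencing batch and the number of cells sorted. All 4 plates carry 1 sequencing batch, and each plate is its own amplification batch, so plate effects cannot be separated from the pools of mice.

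Each plate's table has 34016 rows, of which 92 are spike-ins. Of the other 33924 names, 28577 match a GENCODE M21 symbol and hold 92.2% of the UMIs. Genes are named as in the deposited tables. The 37 mitochondrial rows hold 0 UMIs on every plate, so the planned limit of 25% mitochondrial UMIs removed no cell. Cells were kept from wells listed as holding 1 cell with at least 500 UMIs on mouse genes. No doublet caller was run, and leaving out the 2% of cells with the most UMIs on each plate was tried instead. Wells without a cell held a mean of 1.21 to 1.35% of the median UMIs of wells with one. Replicate plates differed by more than sampling noise, with a chi-square per degree of freedom of 4.18 for OVA/CpG over 5930 genes and 3.51 for BSA/CpG over 4683 genes with at least 20 UMIs, so none was treated as a repeat deposit.

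Cells of all plates were clustered together with scanpy 1.11.5 (scaling to 1000 UMIs per cell, log transform, 2000 variable genes, 20 principal components, 15 neighbours, Leiden resolution 1). Genes of the response lists and of ribosomal proteins, mitochondria, immunoglobulins and spike-ins were kept out of the clustering genes. Clusters were named from marker lists fixed before the data were examined. The level limits that place a cluster were set after the clusters were seen, at 10 Ccr7, 20 Lyz2 or 2 Xcr1 UMIs per 10000. Clusters 3 and 6 have more markers of Langerhans cells or erythroid cells than of migratory DC among their 10 leading genes. The 6 clusters with high Ccr7 are therefore not treated as a named class but as the Ccr7-high clusters, a pool chosen after the clusters were seen, and each cluster with at least 20 cells on every plate (0, 1, 2 and 3) was also tested on its own. The cDC1-like and monocyte-like clusters and cluster 7 were below 20 cells on at least 1 plate and were compared as shares only. The shares have exact Clopper-Pearson 95% intervals, which cover counting error only.

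UMIs were summed per plate, over all cells or over the cells of a cluster set, and the sums were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, default filter on low counts, quasi-likelihood F test, two-sided, OVA/CpG minus BSA/CpG, Benjamini-Hochberg adjusted p of 0.05). Gene lists were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, beside an estimated correlation, with adjustment over the 17 response lists and separately over the 14 marker lists. A list needed 2 measured members, a minimum not fixed beforehand. fry, which asks whether the members of a list move one way on balance, gave an adjusted p of 0.0389 for both interferon lists over all cells and 0.0818 for both in the Ccr7-high clusters. With no count in a group a fold is a lower bound against 3 counts over that group, and with 1 to 3 counts a ratio of summed UMIs is given with its exact binomial interval. Such an interval covers counting error only and not the spread between cells or plates. Cish and Upp1, at 0 in BSA/CpG cells, lie above the medians of their lists at their lower bounds too, so those medians do not depend on the fitted values. CPM values use TMM library sizes. Means ± SD are over 2 plates. The SE of a log2 fold change is not an output of edgeR's test. It was derived as the absolute log2 fold change divided by the square root of F. The SE that DESeq2 fits was larger for each of the 20 genes called in the Ccr7-high clusters. It was 0.336 against 0.239 for Cxcl10, 0.167 against 0.0814 for Actb and 0.528 against 0.255 for AC113316.1.

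The genes named are the 12 most raised and 12 most lowered calls by fold whose groups do not overlap, up to 4 members of each called list and 2 of each other list by smallest p, and a fixed panel of 20 genes, leaving out clone and predicted-gene names and, outside their list, ribosomal protein genes. The rule, the lists, the tests and most alternatives were set before the data were examined. The rule was written for all cells and the 2 largest classes and was applied to all cells and the Ccr7-high clusters, since no other class had 20 cells on each plate. After the data were seen it was extended to the called marker lists. Samhd1, Actb, AC113316.1, Gm13493 and the leading genes of clusters fall outside it and were named after their values were seen.

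The tests were checked on simulated counts drawn from the plates' own means and depths, with 100 genes changed 2-fold and 100 changed 4-fold. Of genes changed 2-fold, 10 of 100 were recovered over all cells and 11 of 100 in the Ccr7-high clusters. Of genes changed 4-fold, 71 of 100 and 76 of 100 were recovered. There were 4 false calls among 89 over all cells and 2 among 99 in the Ccr7-high clusters. A list raised 2-fold as a whole was called with the preset correlation, but had an adjusted p of 0.136 over all cells and 0.122 in the Ccr7-high clusters with an estimated correlation, so that test had little power with 2 plates per group. Of 16 unchanged lists 0 were called by camera with the preset correlation. The simulated genes were drawn independently of each other at a common dispersion, so this cannot show how often lists with correlated members are called falsely. In the Ccr7-high clusters the estimated correlation of the response lists ranged from -0.0895 to 0.483, and was 0.168 for the type I interferon list.

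Alternatives were DESeq2 1.42.0, RLE factors, no count filter, minimums of 250 and 1000 UMIs per cell, no mitochondrial limit, thinning each cell to 500 UMIs, a replicate block, leaving out each plate, equal numbers of cells of each class, Leiden resolutions of 0.5 and 2, and clustering with the response genes kept. Those chosen after seeing the data left out the monocyte-like cluster, the haemoglobin-led cluster, the clusters with leading genes against the name, or Actb and Tmsb4x. For the gene and marker lists, leaving out the 2% of cells with most UMIs, dropping the mitochondrial limit and, in the Ccr7-high clusters, the Leiden resolutions were added after seeing the data as well. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.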

Results

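Single dendritic cells (DC) positive for injected nanoparticles were profiled from the popliteal and inguinal lymph nodes of C57BL/6 mice, 20 h after injection of the particles under the skin of the hock. The particles carried CpG, a DNA adjuvant sensed by Toll-like receptor 9, together with ovalbumin (OVA/CpG) or bovine serum albumin (BSA/CpG). The series title concerns how contact with T cells that recognise the carried antigen affects the DC transcriptome, and the comparison available here is OVA/CpG against BSA/CpG. Each group had 2 plates, and each plate held cells pooled from 2 mice. Every plate had 380 wells with a sorted cell and 4 wells without. Wells of plates OVA/CpG 1 and 2 gave 507918 and 571114 unique molecular identifier (UMI) counts on mouse genes, and those of plates BSA/CpG 1 and 2 gave 380922 and 403095. After the filter of at least 500 UMIs, 286, 292, 269 and 291 cells remained, in the same order, 1138 in all. Their median depth was 1362.5, 1437, 1116 and 1095 UMIs and their median number of detected genes was 647.5, 654, 505 and 517. OVA/CpG cells thus gave more UMIs per cell on both plates, while spike-in UMIs were 52654 and 65800 on these plates and 61142 and 63152 on the BSA/CpG plates. Wells without a cell held 3 to 37 UMIs. The labels do not say whether the pools of a group came from separate mice, so p-values measure the spread between these plates.

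Most cells lay in clusters with high Ccr7, the receptor gene for migration to lymph nodes. Of 9 clusters, 6 had at least 10 Ccr7 UMIs per 10000 and held 926 cells, and they also carried the actin-bundling gene Fscn1 at 31.8 to 62.5 UMIs per 10000. Clusters 0, 1 and 2 were led by genes such as Ccl22, Bcl2l14 and Fabp5. Cluster 3 was led by Mfge8 and the metallothionein genes Mt1 and Mt2, cluster 6 by Banf1 and 4 haemoglobin genes, and the small cluster 8 by Dars. The plates filled these clusters unequally: in the order OVA/CpG 1 and 2 and BSA/CpG 1 and 2, cluster 2 held 58, 68, 52 and 33 cells, cluster 3 held 35, 45, 87 and 52, and cluster 6 held 12, 29, 14 and 98. Cluster 4, with 76 cells, was cDC1-like, led by Plbd1, Ppt1, Ccl6, Xcr1 and Naaa. Xcr1 had a UMI in 28.9% and Clec9a in 14.5% of its cells. Of 12 cDC1 markers, 11 were each found in at least 5% of its cells. So were 8 of 12 neutrophil, 8 of 14 NK cell or ILC and 8 of 20 T cell markers. Whether it also held cells of other types was not tested. Cluster 5, with 56 cells, was monocyte-like, led by Lyz2, S100a8, Chi3l3 and Saa3. Cluster 7, with 80 cells, had low Ccr7 and was led by Atp1b1, Nrgn and Nid1, and was left unnamed. No cluster was led by markers of cDC2, T cells, B cells or plasmacytoid DC.

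Monocyte-like cells came mostly from the OVA/CpG plates. They made up 14.7% of cells on plate OVA/CpG 1 (42 of 286, exact 95% interval 10.8 to 19.3%) and 3.77% on plate OVA/CpG 2 (11 of 292, 1.90 to 6.64%). They made up 0.372% on plate BSA/CpG 1 (1 of 269, 0.00941 to 2.05%) and 0.687% on plate BSA/CpG 2 (2 of 291, 0.0833 to 2.46%). The group means were 9.23% ± 7.72 and 0.530% ± 0.223 (SD, n = 2 plates each), a difference of 8.70 percentage points. Ccr7-high cells made up 76.2% ± 7.93 of OVA/CpG and 86.6% ± 0.519 of BSA/CpG cells (SD, n = 2 plates each). The cDC1-like share was 8.14% ± 1.83 against 5.17% ± 0.471, and that of cluster 7 was 6.39% ± 1.62 against 7.68% ± 0.174 (SD, n = 2 plates each). In all 4 comparisons the two-sided exact permutation test gave p = 0.333 with n = 2 per group, the smallest value this design allows. Plate OVA/CpG 1 set the size of the monocyte-like difference, which was 3.24 points without it and 14.2 points without plate OVA/CpG 2. The cDC1-like difference turned to -1.57 points with a minimum of 250 UMIs per cell, -1.53 with 1000, -0.444 at Leiden resolution 2 and -1.11 with thinned cells. That of cluster 7's class turned to 3.61 points with a minimum of 250 UMIs, 2.50 at Leiden resolution 2 and 1.39 with thinned cells.

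**Figure D1:**
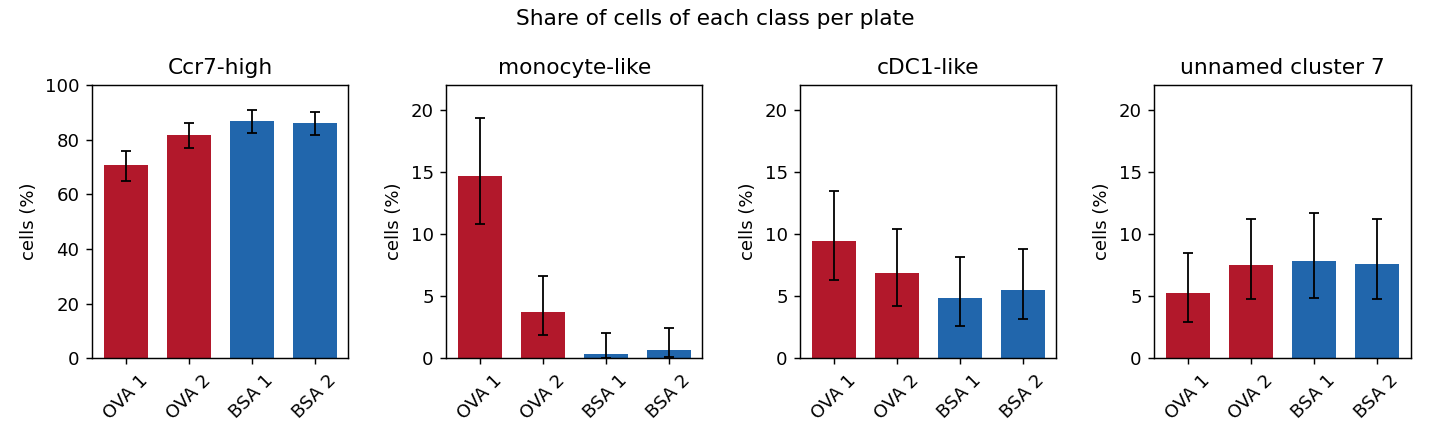
Share of cells (%) in each class on each plate, with exact 95% intervals as error bars; red bars are OVA/CpG plates, blue bars BSA/CpG plates, and the Ccr7-high panel has its own scale. Monocyte-like cells reached 14.7% and 3.77% on the OVA/CpG plates and stayed at 0.372% and 0.687% on the BSA/CpG plates.

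Taken over all cells, OVA/CpG plates had more of the transcripts of inflammatory monocytes and of interferon-stimulated genes, and less of a smaller number of genes that included H2-Ab1. Among the genes of the largest rise were Irg1, the enzyme that makes itaconate, with 187 UMIs against 1 (ratio 129, counting interval 22.8 to 5106), and the acute-phase genes Saa3, at 5.34 ± 0.61 (log2 fold change ± SE), and Hp, at 4.84 ± 0.67. The 4 Saa3 and 5 Hp UMIs of BSA/CpG cells all lay on plate BSA/CpG 2, and the log2 fold changes were 4.41 and 3.91 without plate BSA/CpG 1. The formyl peptide receptor gene Fpr2 and the nucleotide receptor gene P2ry13 had no UMI in BSA/CpG cells and were each at least 10.8-fold higher in OVA/CpG cells, against a floor of 3 counts over the group. Cish, an inhibitor of cytokine signalling, and Upp1, uridine phosphorylase, were at least 6.88-fold and 6.65-fold higher by the same floor. Mgst1 (117 UMIs against 1, ratio 80.5, 14.2 to 3205), Ifitm6 (104 against 2, ratio 35.8, 9.65 to 299.2), Ccr1 (138 against 3, ratio 31.6, 10.6 to 155.3), Cd69 (85 against 2, ratio 29.2, 7.85 to 245.2) and Emilin2 (82 against 2, ratio 28.2, 7.56 to 236.7) rose as well. The lowered genes were led by Ppt1 at -1.38 ± 0.31, Cox6c of respiratory complex IV at -0.89 ± 0.20, the MHC class II gene H2-Ab1 at -0.88 ± 0.19, Apol7c at -0.86 ± 0.20, the nucleolar gene Npm1 at -0.85 ± 0.18 and the small nucleolar RNA host gene Gas5 at -0.80 ± 0.17 (log2 fold change ± SE).

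Of 5559 genes tested over all cells, 102 rose and 16 fell in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. Of the 102 raised genes, 73 were at least 4-fold higher in monocyte-like than in Ccr7-high cells of the OVA/CpG plates. Without the monocyte-like cluster 22 genes were called, 19 raised and 3 lowered, so most of the 16 lowered calls ended too. Of the 22, 20 were among the 118, including Isg15, Cxcl10, Rsad2, Ifit1, Ifit2, Irf7, Bst2, Cox6c and Rpl30. The number of calls was 46 without plate OVA/CpG 1 and 281 without plate OVA/CpG 2, and it was 18 with every cell thinned to 500 UMIs. Without plate OVA/CpG 1 the genes Fpr2, P2ry13, Cish, Upp1, Mgst1, Cd69, Emilin2, Ppt1, Cox6c, H2-Ab1, Apol7c, Igtp, Ccl2, Ccl3, Ccl9, Chi3l3, Fos, Ctsc, S100a8 and Rpl30 were no longer called (edgeR adjusted p from 0.0585 to 0.746). Without plate OVA/CpG 2 this held for P2ry13 and Cdkn1a, without plate BSA/CpG 1 for Cish, Upp1, Cox6c, H2-Ab1, Apol7c, Npm1, Gas5, Cdkn1a and Rpl30, and without plate BSA/CpG 2 for Cish, Upp1, Ppt1, Cox6c, H2-Ab1, Npm1, Gas5, Ifi47, Igtp, Ccl9 and Ctsc. With a plate left out, 1 plate is set against 2, the spread comes from the group with 2 plates and the lone plate is assumed to vary like them, so such counts do not compare directly with those from all plates.

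Within the Ccr7-high clusters, antiviral and other interferon-stimulated genes were higher in OVA/CpG cells. Isg15, a ubiquitin-like modifier, stood at 1408 ± 178 library-scaled counts (CPM) against 453 ± 35.4 (SD, n = 2 plates each), a log2 fold change of 1.63 ± 0.18 (SE, edgeR adjusted p = 0.000871). The chemokine gene Cxcl10 stood at 652 ± 103 against 154 ± 17.7 CPM, a log2 fold change of 2.08 ± 0.24 (edgeR adjusted p = 0.00103). Monocyte-like cells held 111 and 128 Cxcl10 UMIs per 10000 on plates OVA/CpG 1 and 2, against 6.74 and 5.24 in Ccr7-high cells. RNA from monocyte-like cells could add to this rise, and no bound on it was computed for Cxcl10. Rsad2, which encodes viperin, rose by 2.00 ± 0.34, Ifit2 by 1.79 ± 0.27, the guanylate-binding protein gene Gbp5 by 1.77 ± 0.32, Ifitm3 by 1.62 ± 0.27, Bst2 by 1.52 ± 0.25, the transcription factor gene Irf7 by 1.28 ± 0.22 and Samhd1 by 0.87 ± 0.16 (log2 fold change ± SE). Bst2 encodes the protein that antibodies to PDCA-1 bind, and the sort left out PDCA-1 positive cells. Also raised were Ms4a4c at 2.14 ± 0.39, the phosphatase gene Dusp5 at 1.56 ± 0.26, the cell cycle inhibitor gene Cdkn1a at 1.36 ± 0.24, Inpp5b at 1.26 ± 0.24, Tapbp, which encodes the peptide-loading chaperone tapasin, at 0.78 ± 0.15, Fscn1 at 0.70 ± 0.14 and Actb at 0.66 ± 0.08. Cox6c fell by 1.01 ± 0.19 on the log2 scale and the ribosomal protein gene Rpl30 by 0.95 ± 0.18.

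**Figure D2:**
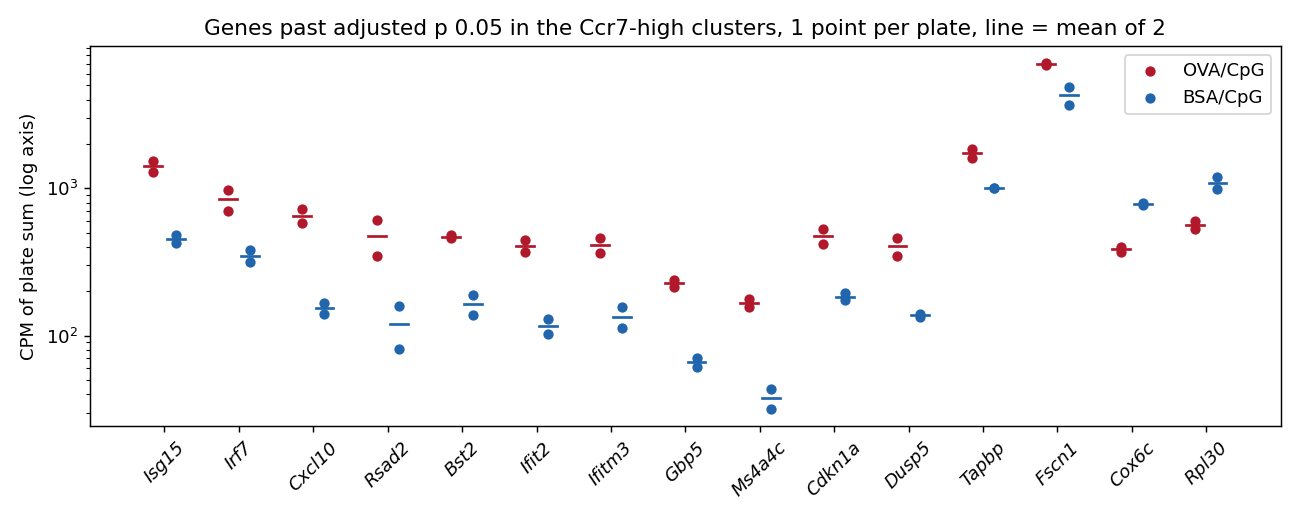
Level of 15 of the 20 called genes in the Ccr7-high clusters, as CPM of the plate sum on a log axis; each point is 1 plate, red for OVA/CpG and blue for BSA/CpG, and each line is the mean of 2 plates. For every gene drawn both points of a group lie on the same side of both points of the other, as for all 20 called genes, so this follows from the choice of genes. Isg15 stood at a mean of 1408 CPM against 453.

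These were among 17 raised and 3 lowered genes of 4248 tested in the Ccr7-high clusters by edgeR's quasi-likelihood test. Besides the named genes, 2 genes with clone or predicted-gene names were called, AC113316.1 among the raised and Gm13493 among the lowered. Raised and lowered genes numbered 14 and 3 with RLE factors, 17 and 5 with DESeq2, 91 and 58 with a replicate block and 68 and 45 with no count filter. Of the 20 genes 16 were also called over all cells. The count rose to 69 without plate OVA/CpG 1, 81 without plate OVA/CpG 2, 169 without plate BSA/CpG 1 and 69 without plate BSA/CpG 2, and fell to 3 with a minimum of 1000 UMIs per cell. With a minimum of 250 UMIs 14 of the 20 were called, and Samhd1 (0.0655), Fscn1 (0.0721), Inpp5b (0.0625), Tapbp (0.0805), Cox6c (0.0524) and Gm13493 (0.0524) were not (edgeR adjusted p). The same 6 genes, Gbp5 (edgeR adjusted p = 0.0561) and Rpl30 (0.0623) were not called without the 2% of cells with most UMIs. Cdkn1a (edgeR adjusted p = 0.0640) and Tapbp (0.0747) were no longer called without plate OVA/CpG 2, and Gm13493 (0.0542) without plate OVA/CpG 1. Without plate BSA/CpG 2, Fscn1 (0.137), Inpp5b (0.0622), Gm13493 (0.0563) and Tapbp (0.0519) were no longer called. With only the clusters whose leading genes do not go against a migratory DC name (0, 1, 2 and 8), 10 of the 20 were called and Irf7 (0.159), Samhd1 (0.0671), Gbp5 (0.128), Ms4a4c (0.141), Cdkn1a (0.0866), Inpp5b (0.0671), Tapbp (0.258), Fscn1 (0.115), Cox6c (0.128) and Rpl30 (0.0989) were not, with fewer cells in the test (edgeR adjusted p). Without cluster 6 alone 15 of the 20 were called, and Irf7 (0.10004), Gbp5 (0.0746), Ms4a4c (0.0799), Inpp5b (0.0613) and Tapbp (0.0946) were not. At Leiden resolution 0.5, 19 of the 20 were called and Ms4a4c was not (log2 fold change 1.67, edgeR adjusted p = 0.0777). With Actb and Tmsb4x left out of the counts, Fscn1 (edgeR adjusted p = 0.0599) and Tapbp (0.0568) were not called. Their log2 fold changes were then 0.70 and 0.78. Fscn1 was lower in clusters 3, 6 and 8 (39.3, 31.8 and 34.7 UMIs per 10000) than in clusters 0, 1 and 2 (62.5, 61.6 and 59.0), and its log2 fold change was 0.58 with clusters 0, 1, 2 and 8 and 0.68 without cluster 6.

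As a group, the type I interferon response genes rose in the Ccr7-high clusters. All 40 measured members had a positive log2 fold change, with a median of 1.02. Of these, 5 passed the test over all genes (Isg15, Rsad2, Ifit2, Bst2 and Irf7), and 24 passed when adjusted over the list alone. Limma's camera with its preset correlation called the list at an adjusted p of 1.0e-26, and the adjusted p was 0.236 with an estimated correlation. The interferon-gamma response list rose too, with a median of 0.53 over 30 members, 2 of them called over all genes (Cxcl10 and Gbp5) and 12 when adjusted over the list alone. Its camera adjusted p was 1.1e-10, and 0.236 with an estimated correlation. Of its other members, Igtp stood at 1.497 ± 0.323, Ifi47 at 0.98 ± 0.22, Gbp2 at 0.62 ± 0.16, Stat1 at 0.46 ± 0.17 and Cxcl9 at 0.15 ± 0.37 (log2 fold change ± SE), none past the edgeR threshold. Cxcl9 turned to -0.50 without plate OVA/CpG 2 and -0.39 without plate BSA/CpG 2.

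In single Ccr7-high cells thinned to 500 UMIs, the median number of UMIs from type I interferon response genes was 3 on both OVA/CpG plates and 1 on both BSA/CpG plates. Cells without any such UMI made up 8.91 and 12.97% on the OVA/CpG plates and 33.3 and 33.9% on the BSA/CpG plates.

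**Figure D3:**
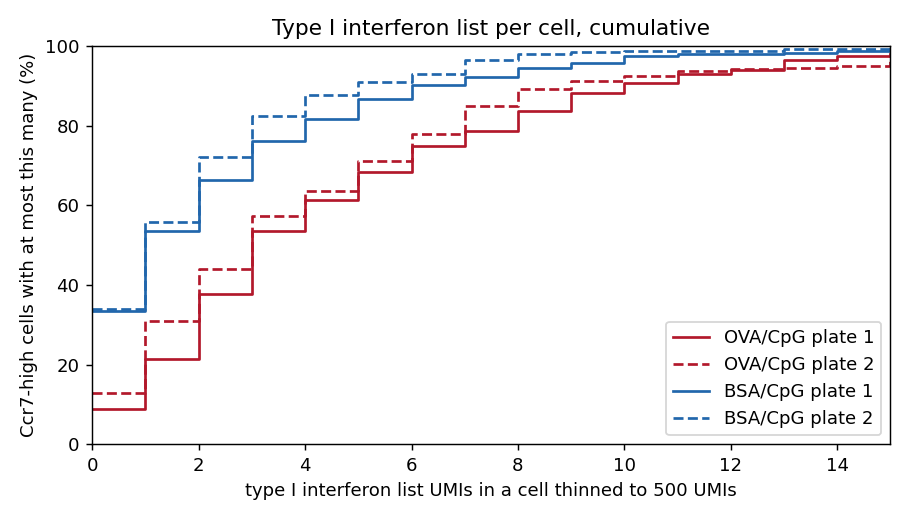
Cumulative percent of Ccr7-high cells on each plate, each cell thinned to 500 UMIs, by the number of UMIs from type I interferon response genes. Red lines are OVA/CpG plates and blue lines BSA/CpG plates. The lines start at 8.91 and 12.97% of OVA/CpG cells and at 33.3 and 33.9% of BSA/CpG cells with 0 such UMIs, and the OVA/CpG lines stay lower.

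Antigen presentation and activation lists were compared in the same clusters. The MHC class I presentation list rose with a median of 0.25 over 26 members, of which Tapbp was called, at a camera adjusted p of 0.0031 (0.323 with an estimated correlation). The CD40 and NF-kB response list rose with a median of 0.22 over 31 members, 0 called over all genes and 2 when adjusted over the list alone, at a camera adjusted p of 0.0099 (0.250 with an estimated correlation). The receptor gene Cd40 itself stood at 0.85 ± 0.20 (edgeR adjusted p = 0.0941), Irf1 at 0.83 ± 0.20, Nfkbia at 0.48 ± 0.18 and Relb at 0.40 ± 0.18. The immediate-early and stress list rose with a median of 0.47 over 17 members, 0 called over all genes and 1 (Klf6) when adjusted over the list alone, at a camera adjusted p of 0.0099 (0.250 with an estimated correlation). Klf6 stood at 0.81 ± 0.19 and Nr4a3 at 0.997 ± 0.393, the latter 0.31 without plate BSA/CpG 2 and 2.20 without plate BSA/CpG 1. Without plate OVA/CpG 2 the camera adjusted p of these 3 lists was 0.087, 0.087 and 0.187, and without plate BSA/CpG 2 that of the CD40 and NF-kB list was 0.143 and that of the immediate-early list 0.171. With a plate left out the medians ranged from 0.12 (without BSA/CpG 2) to 0.33 (without BSA/CpG 1) for the CD40 and NF-kB list, and from 0.22 (without OVA/CpG 2) to 0.53 (without BSA/CpG 1) for the immediate-early list. With cells thinned to 500 UMIs the camera adjusted p was 0.0557 for the CD40 and NF-kB list and 0.406 for the immediate-early list. With clusters 0, 1, 2 and 8 alone the camera adjusted p of the 3 lists was 0.0960 (MHC class I), 0.149 (CD40 and NF-kB) and 0.119 (immediate-early).

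Ribosome and respiratory chain genes fell in the Ccr7-high clusters as a share of UMIs. Mouse UMIs per spike-in UMI were higher on the OVA/CpG plates (mean 9.16 against 6.31, wells with a cell). Whether these transcripts fell in number per cell was not tested. Of 60 cytosolic ribosomal protein genes, 53 had a negative log2 fold change and the median was -0.40. Of these, 1 (Rpl30) was called over all genes and 8 when adjusted over the list alone, and camera gave an adjusted p of 2.3e-10 (0.250 with an estimated correlation). Of 38 oxidative phosphorylation genes, 33 had a negative value and the median was -0.30, with 1 (Cox6c) called over all genes and 5 when adjusted over the list alone, at a camera adjusted p of 1.7e-06 (0.236 with an estimated correlation). Atp5e stood at -0.71 ± 0.19, Uqcrh at -0.75 ± 0.21 and Rps25 at -0.70 ± 0.17 (log2 fold change ± SE), none past the edgeR threshold.

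**Figure D4:**
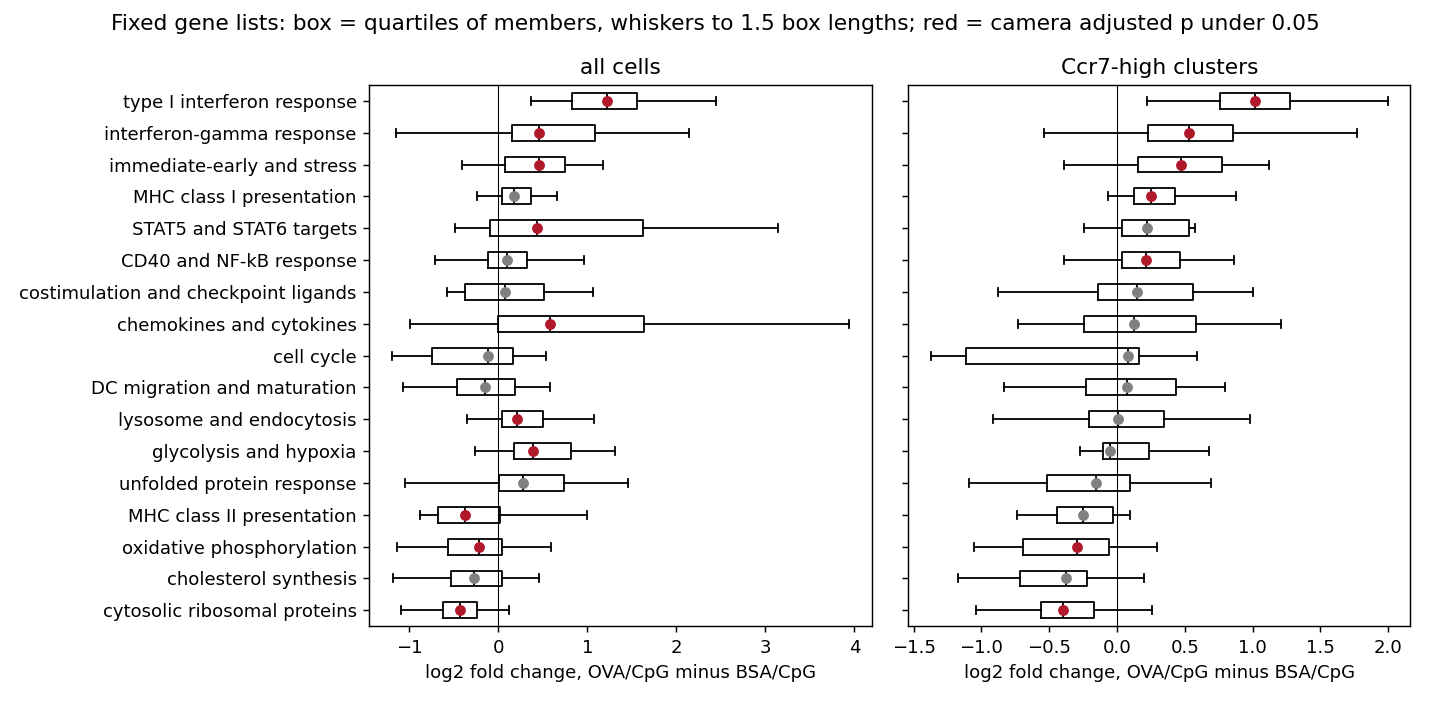
Log2 fold change, OVA/CpG minus BSA/CpG, of the measured members of the 17 fixed gene lists, over all cells and in the Ccr7-high clusters; boxes are quartiles, whiskers reach to 1.5 box lengths, and a dot marks the median, red where camera's adjusted p with the preset correlation was under 0.05. The type I interferon list has the highest median in both panels, 1.22 and 1.02.

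The remaining 10 lists were not called in the Ccr7-high clusters. These covered chemokines and cytokines (median 0.12, camera adjusted p = 0.0587), STAT5 and STAT6 targets (0.22, 0.0948), costimulation and checkpoint ligands (0.14, 0.219), MHC class II presentation (-0.25, 0.219), DC migration and maturation (0.08, 0.216), the unfolded protein response (-0.16, 0.200), cholesterol synthesis (-0.38, 0.207), glycolysis and hypoxia (-0.05, 0.600), lysosome and endocytosis (0.01, 0.490) and cell cycle (0.08, 0.490). For glycolysis and hypoxia and for cell cycle camera's direction was opposite to the sign of the median, and for lysosome and endocytosis the mean of -0.02 was opposite to the median. Values of single genes chosen beforehand were 0.98 ± 0.29 for Cd274, 0.57 ± 0.28 for Cd86, 0.42 ± 0.14 for Ccr7, 0.18 ± 0.16 for Ccl22, 0.06 ± 0.09 for Ccl5, 0.01 ± 0.17 for Socs2, 0.04 ± 0.16 for Il4i1, -0.25 ± 0.30 for Ccl17, -0.58 ± 0.26 for H2-Ab1 and -0.73 ± 0.59 for Il12b (log2 fold change ± SE), none of them past the edgeR threshold. Leaving out 1 plate turned the sign for Ccl17 (0.11 without OVA/CpG 2), Ccl22 (-0.03 without OVA/CpG 1), Socs2 (-0.22 without OVA/CpG 2 and -0.06 without BSA/CpG 2) and Il12b (0.74 without BSA/CpG 1), and H2-Ab1 stood at 0.01 without BSA/CpG 1. Cd80, Ido1 and Ifng had 20, 8 and 3 UMIs in these clusters over the 4 plates and were under the count filter.

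The interferon response was also measured in single Ccr7-high clusters. In tests of each cluster on its own, the median of the type I list was 0.82 in cluster 0, 0.87 in cluster 1, 1.39 in cluster 2 and 0.29 in cluster 3. Camera adjusted p was 0.000315, 2.2e-08, 5.4e-14 and 0.0344, and 0.372, 0.511, 0.187 and 0.489 with an estimated correlation. Only 16, 20, 26 and 14 of the 47 list genes were measured in these clusters, so the medians cover different genes. Of these, 2, 2, 1 and 3 were lower in OVA/CpG cells. The ribosomal list had medians of -0.30, -0.31, -0.21 and -0.15 in these clusters, and was not called in cluster 3 (camera adjusted p = 0.0760). With an estimated correlation its camera adjusted p was 0.372, 0.511, 0.243 and 0.489, so it was called in none of them. The tests of single genes called 1, 2, 1 and 1 genes (edgeR). AC113316.1 was called in each cluster, though in cluster 3 not by DESeq2, and Isg15 in cluster 1 at 1.49 ± 0.25 (log2 fold change ± SE, edgeR adjusted p = 0.0410). At an unadjusted p under 0.05 there were 118, 126, 171 and 79 genes. The calls were 3, 3, 14 and 2 without plate OVA/CpG 1, 6, 0, 2 and 6 without plate OVA/CpG 2, 54, 18, 45 and 4 without plate BSA/CpG 1, and 30, 14, 52 and 4 without plate BSA/CpG 2. Differences between clusters in these responses were not tested.

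Over all cells 10 of the 17 lists were called by camera with the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.211. The type I interferon list had a median of 1.22 over 43 members, 19 called over all genes and 37 when adjusted over the list alone, with Rsad2 at 2.44 ± 0.26, Ifit2 at 2.08 ± 0.25 and Ifit1 at 1.69 ± 0.23 (camera adjusted p = 2.4e-35, and 0.211 with an estimated correlation). The interferon-gamma list had a median of 0.46 over 35 members, 6 called over all genes and 14 when adjusted over the list alone, with Cxcl10 at 3.18 ± 0.28, Fam26f at 2.14 ± 0.32, Igtp at 1.62 ± 0.31 and Ifi47 at 1.11 ± 0.21 (camera adjusted p = 5.8e-11, and 0.211 with an estimated correlation). Chemokines and cytokines had a median of 0.58 over 21 members with 4 called, among them Ccl3 (65 UMIs against 3, ratio 14.9, 4.88 to 74.1), Ccl2 (70 against 3, ratio 16.04, 5.27 to 79.7) and Ccl9 at 1.64 ± 0.38 (camera adjusted p = 1.8e-06, and 0.211 with an estimated correlation). Among STAT5 and STAT6 targets (median 0.43 over 12 members, camera adjusted p = 0.0024, and 0.326 with an estimated correlation) the called genes were Cish, Cdkn1a at 1.29 ± 0.26 and Chi3l3 at 3.14 ± 0.67. The median of this list was -0.0861 with cells thinned to 500 UMIs, 0.21 without plate OVA/CpG 2 and 0.79 without plate BSA/CpG 2. Chi3l3, a secreted lectin gene of monocytes and macrophages, had no UMI on plate BSA/CpG 1 and stood at 2.16 without that plate, and at -0.94 without the monocyte-like cluster.

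Immediate-early and stress genes (median 0.45, 1 of 21 called, Fos with 57 UMIs against 3, ratio 13.1, 4.25 to 65.2), glycolysis and hypoxia (0.39, 0 of 14 called) and lysosome and endocytosis (0.21, 1 of 24 called, Ctsc at 1.07 ± 0.25) were the other raised lists over all cells, at camera adjusted p of 0.0024, 0.0425 and 0.0466 (0.326, 0.326 and 0.402 with an estimated correlation). Without the monocyte-like cluster the medians of the glycolysis and lysosome lists were -0.03 and -0.05. The lowered lists were cytosolic ribosomal proteins (median -0.43, 1 of 61 called and 17 when adjusted over the list alone), oxidative phosphorylation (-0.22, 1 of 39 called) and MHC class II presentation (-0.38, 1 of 15 called), at camera adjusted p of 5.8e-11, 0.0041 and 0.0185 (0.326 for each with an estimated correlation). Calls ended without plate OVA/CpG 1 for glycolysis (0.078) and lysosome (0.119), without plate OVA/CpG 2 for oxidative phosphorylation (0.058), without plate BSA/CpG 1 for STAT5 and STAT6 targets (0.090), glycolysis (0.123) and lysosome (0.251), and without plate BSA/CpG 2 for the immediate-early list (0.073), all as camera adjusted p. Medians moved most to 1.13 without plate OVA/CpG 2 and 1.002 without plate BSA/CpG 1 for chemokines, -0.61 without OVA/CpG 2 for MHC class II, 0.22 without BSA/CpG 2 for the immediate-early list, 0.63 without BSA/CpG 2 for glycolysis, and 0.08 without OVA/CpG 1 and 0.37 without BSA/CpG 2 for lysosome. With cells thinned to 500 UMIs 5 lists were no longer called: MHC class II presentation (0.130), STAT5 and STAT6 targets (0.292), immediate-early and stress (0.148), glycolysis and hypoxia (0.292) and lysosome and endocytosis (0.148), as camera adjusted p. Without the 2% of cells with most UMIs the MHC class II, glycolysis and lysosome lists were not called (camera adjusted p = 0.0751 for each). The calls of glycolysis and lysosome also ended without the monocyte-like cluster (camera adjusted p = 0.512 and 0.567) and with equal numbers of cells of each class (0.719 and 0.475). The lysosome call ended with a minimum of 250 UMIs (camera adjusted p = 0.0536). The glycolysis call ended with a minimum of 1000 (camera adjusted p = 0.0967). The 7 lists not called over all cells were CD40 and NF-kB response (median 0.09, camera adjusted p = 0.426), MHC class I presentation (0.18, 0.0717), costimulation and checkpoint ligands (0.07, 0.694), DC migration and maturation (-0.15, 0.224), the unfolded protein response (0.28, 0.217), cholesterol synthesis (-0.27, 0.244) and cell cycle (-0.12, 0.224).

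Marker lists of other cell types were compared in the same way. Over all cells monocyte markers rose, with a median of 3.14 and 10 of 11 members called, among them Lyz2 at 3.44 ± 0.41, Plac8 at 2.52 ± 0.29 and Fn1 at 3.62 ± 0.52 (camera adjusted p = 1.3e-29, and 0.498 with an estimated correlation). Neutrophil markers rose, with a median of 2.07 and 2 of 6 members called, Lcn2 at 3.73 ± 0.53 and S100a8 at 2.58 ± 0.60 (camera adjusted p = 5.7e-08, and 0.498 with an estimated correlation), and S100a8 was a leading gene of the monocyte-like cluster. S100a8 stood at 1.69 without plate BSA/CpG 1 and 5.28 without plate BSA/CpG 2, and the neutrophil median at 1.14 and 5.12. Without that cluster the neutrophil list was not called (camera adjusted p = 0.188). The cDC1 markers fell, with a median of -0.78 over 10 members and Ppt1 called, at a camera adjusted p of 0.0051 (0.498 with an estimated correlation, 0.122 without plate OVA/CpG 1, 0.133 without plate BSA/CpG 2, 0.185 without the 2% of cells with most UMIs and 0.436 with cells thinned to 500 UMIs). Xcr1 stood at -1.39 ± 0.54 and at -0.0143 without plate BSA/CpG 2, whose level set the difference. The share of cDC1-like cells ran the other way, at 8.14% against 5.17%. In the Ccr7-high clusters the plasmacytoid DC list was called on 2 measured members, Bst2, which is also in the type I interferon list, and Tcf4 at 0.57 ± 0.38 (camera adjusted p = 0.0075, 0.692 with an estimated correlation). Monocyte markers there had a median of 0.31 and a mean of 0.65 over 5 members, all 5 higher in OVA/CpG cells. Of these 1 was called, Ms4a4c, and the list was not called (camera adjusted p = 0.125).

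The other marker lists were not called. Over all cells their medians and camera adjusted p were -0.09 and 0.313 for migratory DC, 0.19 and 0.592 for cDC2, -0.56 and 0.188 for Langerhans cells, 0.47 and 0.313 for macrophages, 0.43 and 0.0685 for plasmacytoid DC, 0.08 and 0.592 for T cells, -0.18 and 0.313 for NK cells, -0.29 and 0.422 for erythroid cells, and -0.12 and 0.313 for cycling cells. For erythroid cells camera's direction was up, opposite to the sign of the median, in both comparisons. In the Ccr7-high clusters they were 0.16 and 0.362 for migratory DC, -0.37 and 0.351 for cDC1, -0.46 and 0.574 for cDC2, -0.31 and 0.351 for Langerhans cells, 0.18 and 0.574 for T cells, 0.15 and 0.351 for neutrophils, -0.29 and 0.385 for erythroid cells, and 0.08 and 0.547 for cycling cells. B cell and stromal markers had fewer than 2 measured members in both comparisons, as had macrophage and NK cell markers in the Ccr7-high clusters.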

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

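Of the tests here, the gap between the OVA/CpG plates in monocyte-like share, the RNA bounds from genes other than Lyz2 the share taken by Actb and Tmsb4x and the count of marker-positive wells as monocyte-like were chosen after the results were seen, and the other tests were written before theirs. Signals outside the main comparisons stood out. Mouse UMIs per spike-in UMI, which the comparisons do not use, were 9.65 and 8.68 on the OVA/CpG plates and 6.23 and 6.38 on the BSA/CpG plates (9.16 ± 0.684 against 6.31 ± 0.108, SD, n = 2 plates each), a ratio of 1.45. Wells with at least 100 but under 500 UMIs, left out by the filter, held 78.5 ± 13.8 UMIs of type I interferon response genes per 10000 on the OVA/CpG plates and 46.0 ± 4.13 on the BSA/CpG plates (SD, n = 2 plates each), a ratio of 1.71. There were 60, 48, 81 and 72 such wells on plates OVA/CpG 1 and 2 and BSA/CpG 1 and 2. In the same order they held 25, 1, 13 and 9 Cxcl10 UMIs and 12, 6, 8 and 5 Isg15 UMIs. Cxcl10 thus did not follow the list on plate OVA/CpG 2.

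Type I interferon response genes were higher in OVA/CpG cells of the Ccr7-high clusters, with a list median of 1.02 on the log2 scale. These plates also gave more UMIs per cell. With cells thinned to 500 UMIs the median was 0.978 (camera adjusted p = 7.7e-20), so it did not rest on the weight of cells with many UMIs. Thinning keeps each cell's expected composition, so it cannot decide whether depth itself shaped the counts. Monocyte-like cells, rich in these genes, could shed RNA into other wells. The Lyz2 level in Ccr7-high wells allows such RNA at most 8.68% of the list's rise on either OVA/CpG plate (upper 95% counting bound). Ms4a4c, itself a called gene and the most permissive of 12 genes, allows at most 49.8%. These bounds take the monocyte-like cells of the same plate as the source. Monocyte transcripts in Ccr7-high cells did not follow the number of those cells. On plates OVA/CpG 1 and 2 and BSA/CpG 1 and 2, S100a8 stood at 2.73, 3.65, 0.501 and 5.32 UMIs per 10000. Lyz2 stood at 1.59, 0.485, 0.534 and 0.914, so the source is not settled. A different mix of clusters is argued against as the whole cause by the rise within each of clusters 0 to 3, for the list genes measured there. The lowest median was 0.290 in cluster 3, over 14 genes. Depth, the carried antigen, any T cell response to it, and a difference between mouse pools or plates remain open, since each plate holds 1 group and 1 pool.

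Monocyte-like cells lay mostly on the OVA/CpG plates, with 42 and 11 cells against 1 and 2. As a test of whether those of the BSA/CpG plates fell under the UMI minimum, the share of wells of at least 100 but under 500 UMIs with at least 2 monocyte marker UMIs was 18.3 and 10.4% on the OVA/CpG plates and 7.41 and 18.1% on the BSA/CpG plates, a mean difference of -1.64 points. With every such marker-positive BSA/CpG well counted as monocyte-like and none on the OVA/CpG plates, the BSA/CpG shares were 2.00 and 4.13% (upper 95% bound at most 6.72%) against 12.1% (8.89 to 16.1%) on plate OVA/CpG 1, which argues against such wells for that plate and leaves plate OVA/CpG 2 (3.24%) open. The OVA/CpG plates differed from each other by 10.9 points, more than the 3.08 points between plate OVA/CpG 2 and the nearer BSA/CpG plate. A sort gate or mouse pool that differed between plates may therefore contribute and cannot be told apart from an effect of the antigen, for want of more plates.

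Ribosomal protein genes were lower as a share of UMIs in OVA/CpG cells of the Ccr7-high clusters, with a list median of -0.395. Their number per cell against the spike-ins was not tested. Actb and Tmsb4x took 7.72 and 7.66% of UMIs on the OVA/CpG plates and 6.55 and 6.36% on the BSA/CpG plates, which shifts all other genes by -0.0211 at most on the log2 scale, or 5.34% of the list median. Against a bias by transcript length, 1188 genes of like length and expression (within 0.5 and 1 on the log2 scale, limits set after the data were seen) had a median of 0.0239, which is -6.06% of the list's. With cells thinned to 500 UMIs the median was -0.264 (camera adjusted p = 7.2e-05). Thinning keeps each cell's expected composition, so it cannot decide how far depth shaped the counts. Depth, a change in the cells, by antigen or by mouse pool, and an effect of the plate remain open.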

How the results depend on the processing

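Alternatives that left out the monocyte-like cluster, the haemoglobin-led cluster, clusters with leading genes against the name, or Actb and Tmsb4x were chosen after the results were seen, as were, for lists, leaving out the 2% of cells with most UMIs, no mitochondrial limit and (Ccr7-high) the Leiden resolutions. The type I interferon, interferon-gamma and ribosomal lists kept their direction and their camera calls in both comparisons under every alternative with the preset correlation. With an estimated correlation 0 lists were called in any of the 4 families, all cells or Ccr7-high clusters, response or marker lists. That test had little power here, as the simulated data show. In the Ccr7-high clusters the estimated correlation lay above the preset 0.01 for the type I interferon (0.168) and ribosomal (0.104) lists, and below it for oxidative phosphorylation (0.0059). There fry passed 0.05 for no response list (lowest adjusted p = 0.0818). Over all cells fry called the interferon lists only, and gave the ribosomal list an adjusted p of 0.114. The 56 called named genes kept their direction in all but 2 of 823 alternatives and were no longer past the threshold in 176. The groups did not overlap for 117 of 118 calls over all cells and 20 of 20 in the Ccr7-high clusters. Leaving out a plate could thus hardly turn a sign, and several other alternatives refit the same counts, so a kept direction is weak support. The mitochondrial limit removed no cell, so it cannot show stability. Without Actb and Tmsb4x, Fscn1 and Tapbp lost their calls (Ccr7-high).

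Over all cells 118 genes were called, and the count was 253 (117 shared) with no count filter, 70 (69) with a minimum of 250 UMIs, 18 (18) with cells thinned to 500 UMIs, 26 (20) with equal numbers of cells of each class, and 22 (20) without the monocyte-like cluster. Leaving out a plate gave 46 (without OVA/CpG 1) to 281 (without OVA/CpG 2). In the Ccr7-high clusters 20 genes were called, and the count was 113 with no count filter, 14 with a minimum of 250 UMIs, 3 with 1000, 12 without the 2% of cells with most UMIs and 5 with thinned cells (AC113316.1, Actb, Cxcl10, Irf7 and Isg15). With only clusters 0, 1, 2 and 8 it was 14 (10 shared), with 4 of the 7 called lists kept, and without the haemoglobin-led cluster 16 (15 shared). Leaving out a plate gave 69 (without OVA/CpG 1 or BSA/CpG 2) to 169 (without BSA/CpG 1). RLE factors ended the calls of Fscn1, Inpp5b and Tapbp, and DESeq2 gave Gbp5 and Ms4a4c no adjusted p. Thinning and fewer cells leave fewer counts, and thinning also left fewer genes tested (2432 of 5559 over all cells and 1961 of 4248). For the other changes the cause was not tested.

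Clusters 0 to 3 gave 12, 8, 12 and 2 genes with no count filter, where the median of all genes was shifted by 0.455, 0.406, 0.348 and -0.176 on the log2 scale. Cluster 1 gave 1 with RLE, cluster 2 gave 2 and cluster 3 gave 0 with DESeq2, so AC113316.1 was lost there (79 at an unadjusted p under 0.05 in edgeR). Leaving out a plate gave 3 to 54, 0 to 18, 2 to 52 and 2 to 6. Thinning left 5 of the 10 lists called over all cells (both interferon lists, chemokines, oxidative phosphorylation and ribosomal proteins). Leaving out a plate gave 7 to 11 called lists, 7 to 9 of them among the 10. In the Ccr7-high clusters 7 lists were called, and leaving out a plate gave 4 (without OVA/CpG 2) to 8. Leaving out a plate gave 2 to 4 marker lists over all cells and in the Ccr7-high clusters. The plasmacytoid DC call there was lost (0 lists called) with no count filter and with thinned cells. The STAT5 and STAT6 list over all cells turned to -0.0861 with thinned cells, and the glycolysis and lysosome lists to -0.0265 and -0.0455 without the monocyte-like cluster. Chi3l3 turned to -0.78 with equal numbers of cells of each class and -0.94 without the monocyte-like cluster. The alternatives behind the last 4 values by construction leave out all or most monocyte-like cells, and for the STAT5 and STAT6 list the cause was not tested.

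Monocyte-like and Ccr7-high shares kept their direction under the UMI minimums, clusterings and thinning tried, with differences of 8.49 to 10.7 and -11.1 to -8.67 percentage points. Leaving out a plate gave 3.24 (without OVA/CpG 1) to 14.2 (without OVA/CpG 2) and -16.0 to -4.77. The cDC1-like difference was -1.57 with a minimum of 250 UMIs, -1.53 with 1000, -0.444 at Leiden resolution 2 and -1.11 with thinned cells, against 1.68 to 4.28 with a plate left out. That of cluster 7's class was 3.61 with a minimum of 250 UMIs, 2.50 at resolution 2, -0.035 with the response genes kept and 1.39 with thinned cells, against -2.44 to -0.149 with a plate left out. The cause was not tested.

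Replicate numbers in the labels are not known to pair plates. Differences between replicates 1 and 2 correlated at r = -0.0862 between the groups over 2721 genes, which are not independent. With a replicate block 219 genes were called over all cells, 149 in the Ccr7-high clusters, 0, 1, 0 and 1 in clusters 0 to 3, and 2 marker lists in the Ccr7-high clusters. AC113316.1 was then not called in clusters 0 and 2, nor the lysosome list over all cells (camera adjusted p = 0.0519).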

Other observations

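Cluster 7, Aire, the interferon genes and the clone-named gene were singled out after their values were seen, and the test on single cells was written before its result. Cluster 7 held 15, 22, 21 and 22 cells of plates OVA/CpG 1 and 2 and BSA/CpG 1 and 2, in that order. Aire, the transcriptional regulator best known from the thymus, had a UMI in 9 of its 80 cells (11.2%, exact 95% interval 5.28 to 20.3%), in 1 of 76 cells of the cDC1-like cluster and in 1 of 219 cells of cluster 3, at median depths of 1301.5, 1952.5 and 1057 UMIs. It had a UMI in 0 cells of the other 6 clusters. Of the 80 cells, 55.0% had a UMI of the class II chaperone gene H2-DMb2, 56.2% of Atp1b1, 35.0% of Nid1, 22.5% of Gal and 16.2% of Ccr7.

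Ifng gave 69 UMIs on plate OVA/CpG 1 in 7 cells, 63 of them in 1 cell, 1 UMI on plate OVA/CpG 2 and 0 on both BSA/CpG plates. Of the 69, 64 lay in 2 cells of the cDC1-like cluster, where Gzma also had a UMI in 4 cells. Ifnb1 had 0 UMIs on all 4 plates.

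AC113316.1, a gene with a clone name, had the smallest p in the Ccr7-high clusters together and in each of clusters 0 to 3. Its log2 fold change was 2.39 ± 0.25 (SE, edgeR adjusted p = 0.000871), with 904 and 1979 UMIs on the OVA/CpG plates and 273 and 160 on the BSA/CpG plates in the Ccr7-high clusters. What it encodes was not examined.

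The interferon response may be spread over most Ccr7-high cells of the OVA/CpG plates rather than held by a few. With each cell thinned to 500 UMIs, cells held a mean of 4.60 and 4.17 UMIs of the type I list on the OVA/CpG plates and 2.42 and 1.99 on the BSA/CpG plates, with medians of 3, 3, 1 and 1. Leaving out the 10% of cells with most list UMIs on each plate kept 86.9% of the difference between groups, which argues against a small subset as the source. Cells with 0 list UMIs made up 8.91 and 12.97% on the OVA/CpG plates and 33.3 and 33.9% on the BSA/CpG plates. Isg15 had a UMI in 37.6 and 29.3% of thinned cells against 14.1 and 13.5%, and Cxcl10 in 18.8 and 16.7% against 2.99 and 5.18%. Free RNA can add to such shares, and Lyz2, a gene of monocytes, had a UMI in 7.43 and 2.93% against 2.14 and 3.59% of the same thinned cells.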
